A study of Mus musculus with 6 samples.

How the data were processed

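Bulk RNA sequencing of mouse retinal pigment epithelium (RPE), the pigmented layer that supports the photoreceptors and clears their shed outer segments, was analysed in 3 wild-type (WT) and 3 Abca4-/- (Abca4KO) mice. Per the labels' protocols, RNA was isolated with the RNAqueous-Micro kit and libraries were made with the NEBNext Ultra RNA kit. Whether the libraries kept strand information is not given in the sources used here. Per the labels' protocols, the WT mice were of the strain 129S1/SvlmJ and the Abca4KO mice were the Jackson line with the Abca4tm1Ght allele, so that the line and the genotype change together.

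The authors deposited a table of raw read counts per gene, whole numbers that are not normalized, with 54532 Ensembl genes and 1 column per library. STAR, HTSeq and the mouse build mm10 are named, without versions, in the submitters' processing notes. The annotation release is not given in the sources used here. Of the 54495 gene identifiers shared with GENCODE M21, 53585 (98.33%) had the same coordinates and strand, and coordinates are printed as the deposited table gives them. Gene symbols are also those of the deposited table. The count of a gene depends on how reads that match several genes or overlapping genes were assigned, and without stated strand use a gene and an antisense partner cannot be told apart. Counts of Kcnj13 (31405, with 8844 in its partner Gigyf2), Rb1cc1 (7155, with 501), Tfap2a (1028, with up to 192 in 1 partner) and Cubn (1936, with 161) are uncertain for this reason. Abca4, Optn, Mertk, Npr1, Gucy1a1, Itgav, Lrat, Lrp1, Ctss and Igkc also overlap genes with counts, at most 275 over the 6 libraries for 1 partner, and are uncertain to that extent. Other uncertain genes are named beside their values. The search for overlaps covered Gm9347, Gm7901 and the genes named by rule, with list examples only where their unadjusted p was under 0.05. Further genes were not searched.

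Total counts lay between 17047286 and 19841307 per library. A count of 3 corresponded to between 0.152 and 0.174 CPM, the gene's count scaled to a common library size, and reads carry no molecular identifiers, so such floors cover counting error only. All pairs of libraries differed by more than counting noise: the chi-square statistic per degree of freedom over genes was at least 13.5, and no library was counted as a copy of another. Each library came from a separate mouse, per the series design.

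Genes were filtered with filterByExpr in edgeR 4.0.16 (R 4.3.3), with a minimum count of 10 and the genotypes as groups, which kept 17340 genes. Library sizes were scaled by the trimmed mean of M-values (TMM), and Abca4KO was compared with WT by edgeR's 2-sided quasi-likelihood test over all 6 libraries with no covariate. P-values were adjusted by the Benjamini-Hochberg method and 0.05 was the threshold. Fold changes are Abca4KO minus WT on the log2 scale, with edgeR's prior count of 0.125. The standard error (SE) is the log2 fold change divided by the square root of the quasi-likelihood F statistic. CPM values use TMM-scaled library sizes.

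A total of 36 gene lists, with 965 symbols of which 891 were tested, was written before the data were examined, as were the design, most of the other settings tried and the rule for named genes. Lists were tested with camera in limma 3.58.1 on voom values with a preset inter-gene correlation of 0.01, and adjusted over the 36 lists. Camera compares a list with all other genes. Camera with an estimated correlation and the rotation test fry, which asks whether a list's genes move without comparing them with other genes, were the alternatives. List levels per library are means of log2 CPM with a prior count of 1. The exact permutation test of 3 against 3 libraries cannot give a p below 0.1.

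Named genes were chosen by rule. Abca4, Optn, Tfeb, Rpe65 and Mertk were always named. Of the genes past the threshold with a mean of at least 1 CPM, the libraries of one genotype all above those of the other and a symbol that was not a Gm number, a Rik clone name or an annotated pseudogene, up to 12 per direction were named by fold change. Where fewer than 5 passed in a direction, the 5 smallest p-values under the same symbol and CPM rule were named as well. Up to 4 members of each list with the smallest p-values served as examples. Gm9347, Gm7901, Gm13337, Gm7665, S100a11, Phgdh, Ighg2c, Krt5, Ints6, Csf1r, Ptprc, Cx3cr1, Cd163l1 and Gigyf2 fall outside this rule and were chosen after their values were seen.

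The other settings fixed at that point were other size factors, other filters on low counts, DESeq2 1.42.0, limma-voom with sample weights, the replicate number as a block, each library left out, a test against a 1.5-fold change, scaling without the 100 most abundant genes and a rod marker covariate. A fit without WT 2 and Abca4KO 1, a robust fit and a fit without chromosome 3 were chosen after the data were seen. Similar sequences among GENCODE M21 transcripts were searched with BLAST+ 2.17.0, at 85% identity or more over at least 50% of the query. Figures were drawn with matplotlib.

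The test was tested on simulated data with known changes, drawn from the means and library sizes of these 6 libraries over 17340 genes in 5 simulations. For Abca4KO against WT, it recovered 6.57% of genes changed 1.5-fold, 37.3% of those changed 2-fold and 71.2% of those changed 4-fold. Of its calls there, 9.91% were genes that had not been changed, more than the nominal 5%. Camera called a list shifted by 0.15 on the log2 scale in 3 of 5 simulations, and called 1 of 175 unshifted lists; the simulated genes were drawn independently, so this does not cover correlated genes.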

Results

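The transcriptome of the RPE was measured in 3 WT and 3 Abca4KO mice, all sampled 5 h after light onset. The series title concerns how lysosomes form and how the retina clears phagocytosed material. The comparison asks which RPE transcripts differ between Abca4KO and WT mice, whose line and genotype change together. Abca4 encodes a transporter that moves retinoids across photoreceptor disc membranes and is also expressed in the RPE. Total counts were 19064167, 19075335 and 18146027 in WT replicates 1, 2 and 3, and 19410214, 19841307 and 17047286 in Abca4KO replicates 1, 2 and 3. Mitochondrially encoded genes took between 5.79% and 8.92% of the counts. Ptgds, Ttr, Rgr and Clu were among the 10 most abundant genes.

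Abca4 transcript fell 26.3-fold in the Abca4KO libraries, from 952 ± 18.1 CPM (SD, n = 3) in WT to 36.2 ± 3.31 CPM (SD, n = 3). The 3 WT libraries held 955, 932 and 968 CPM and the 3 Abca4KO libraries 32.6, 39.1 and 36.8 CPM, so each library matched its genotype label. The log2 fold change was -4.72 (SE 0.10), with an adjusted p of 4.48e-06 in edgeR's quasi-likelihood test. Abca4 (ENSMUSG00000028125) lies on chromosome 3 from 122044443 to 122180123 on the plus strand in mm10. The remaining signal amounted to 633 to 758 raw counts per Abca4KO library.

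Beyond Abca4, Bcan, Slco1c1 and Cep83os rose in the Abca4KO RPE and Npr1 fell. The count of Tpm3-rs7 rose too, but may include reads of its near-identical copy Tpm3. Bcan, which encodes the brain extracellular matrix proteoglycan brevican, rose 5.00-fold, from 15.4 ± 3.36 to 77.3 ± 8.24 CPM (SD, n = 3 each). Slco1c1, which encodes a thyroid hormone transporter, rose 2.50-fold, from 51.7 ± 8.28 to 129.2 ± 5.38 CPM (SD, n = 3 each). Npr1, the receptor of atrial natriuretic peptide, fell 2.29-fold, from 184.9 ± 20.8 to 80.9 ± 5.57 CPM (SD, n = 3 each). In all, 8 of 17340 tested genes passed the threshold, 6 of them higher and 2 lower in Abca4KO, and in each of the 8 the libraries of the genotypes did not overlap.

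Bcan (chromosome 3, 87987531 to 88000230) had a log2 fold change of 2.32 (SE 0.18, adjusted p = 0.00920). Slco1c1 (chromosome 6, 141524368 to 141570177) had one of 1.32 (SE 0.12, adjusted p = 0.0247), and Npr1 (chromosome 3, 90450591 to 90465866) one of -1.19 (SE 0.11, adjusted p = 0.0196). The non-coding Cep83os (chromosome 10, 94671025 to 94688576) rose 2.94-fold, from 7.85 ± 1.25 to 23.1 ± 0.293 CPM (SD, n = 3 each, log2 fold change 1.56, SE 0.15, adjusted p = 0.0268), and overlaps the sparsely counted Gm49167 on the opposite strand. Tpm3-rs7 (chromosome 14, 113314608 to 113316754) rose 12.3-fold, from 8.78 ± 4.17 to 108.4 ± 19.1 CPM (SD, n = 3 each, adjusted p = 0.0196). Its sequence was 99.1% identical to Tpm3, so its count and that of Tpm3 are uncertain. The other 2 were the processed pseudogenes Gm9347 on chromosome 7 (log2 fold change 4.49, SE 0.27, adjusted p = 0.00388) and Gm7901 on chromosome 8 (log2 fold change 2.48, SE 0.17, adjusted p = 0.00612). They were 97.4% and 98.7% identical to Phgdh, which encodes the first enzyme of serine synthesis, and their counts are uncertain for the same reason.

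**Figure D1:**
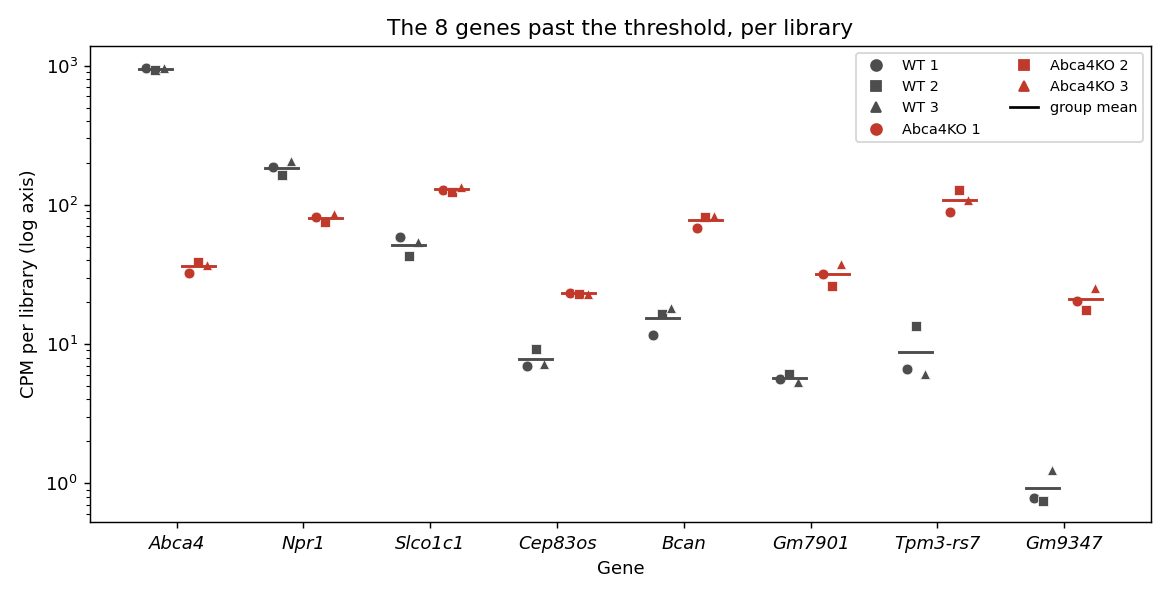
CPM (log axis) of the 8 genes past the threshold (horizontal axis), 1 point per library with grey for WT and red for Abca4KO, marker shapes for replicates and bars for group means. Abca4 lies between 932 and 968 CPM in WT and between 32.6 and 39.1 CPM in Abca4KO, and the genotypes do not overlap in any of the 8 genes.

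At an unadjusted p under 0.05, 1217 genes differed (546 higher, 671 lower), where 867 would do so with no change. Of the other splits of the 6 libraries into 3 and 3, the highest gave 2740 and the rest 253 to 1131. The genotypes did not overlap in 12.8% of tested genes, against 10% by chance for 3 against 3. Leaving out single libraries gave 3 to 11 genes past the threshold. It was 4 without WT 1, 3 without Abca4KO 2 and 3 without Abca4KO 3. Abca4 and Gm9347 passed in all 6 of these fits. Bcan was lost without Abca4KO 2 and without Abca4KO 3, Gm7901 without WT 1, and Tpm3-rs7 passed only without WT 2 and without WT 3, while Npr1, Slco1c1 and Cep83os passed only without WT 2. Cep83os also did not pass with the replicate number as a block (adjusted p = 0.0976).

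Several genes came close without passing. Gucy1a1, a subunit of the nitric oxide receptor guanylate cyclase, measured 14.4 ± 0.683 CPM in WT and 30.0 ± 3.07 CPM in Abca4KO (SD, n = 3 each, adjusted p = 0.0648). Tpm3 measured 145.0 ± 55.4 CPM in WT and 30.2 ± 4.86 CPM in Abca4KO (SD, n = 3 each, log2 fold change -2.26, adjusted p = 0.0723). Serpine3 measured 63.3 ± 17.4 against 16.96 ± 2.45 CPM (SD, n = 3 each, adjusted p = 0.0723), and it overlaps Ints6 on the opposite strand, so its count is uncertain. Cubn, an endocytic receptor that works with Lrp2, measured 23.6 ± 3.09 against 10.9 ± 1.21 CPM (SD, n = 3 each, adjusted p = 0.150).

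Of the genes always named by rule, those other than Abca4 did not pass. Optn, the autophagy receptor of the series title, measured 111.3 ± 10.97 CPM in WT and 109.9 ± 9.31 CPM in Abca4KO (SD, n = 3 each, log2 fold change -0.02, SE 0.10, adjusted p = 0.984). Tfeb, a transcription factor of lysosomal genes, had a log2 fold change of 0.09 (SE 0.13, adjusted p = 0.925). Rpe65, the isomerase of the visual cycle, had one of -0.07 (SE 0.12, adjusted p = 0.936). Mertk, the receptor for ingestion of outer segments, measured 247.8 ± 15.9 against 200.6 ± 10.4 CPM (SD, n = 3 each). All 3 Abca4KO libraries lay below all WT libraries for Mertk, with an adjusted p of 0.589.

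Lysosomal genes were slightly higher as a group in the Abca4KO libraries, as were lists of endothelial (median log2 fold change 0.59), fibroblast (0.21) and macrophage markers (0.22). With an estimated correlation these marker lists did not pass in camera (adjusted p = 0.823 for endothelial and fibroblast, 0.915 for macrophage markers). Mean levels of endothelial and macrophage markers overlapped between the genotypes. Of 56 tested lysosomal enzymes and membrane proteins, 50 had a positive log2 fold change, with a median of 0.12, and the list rose in camera with the preset correlation (adjusted p = 7.76e-07) but not with an estimated correlation (adjusted p = 0.823). Mean levels of the list overlapped between the genotypes, with Abca4KO 1 at 6.899 and WT 2 at 6.950 log2 CPM (exact permutation p = 0.2). Among them the protease gene Ctsl measured 365 ± 20.9 CPM in WT and 508.5 ± 54.3 CPM in Abca4KO (SD, n = 3 each). Of 21 subunits of the V-ATPase, the proton pump that acidifies lysosomes, 19 were positive with a median of 0.12, and that list rose as well with the preset correlation (adjusted p = 2.33e-04; adjusted p = 0.823 with an estimated correlation; exact permutation p of the mean level 0.1). Atp6v0d2 measured 48.3 ± 8.93 against 96.7 ± 33.0 CPM and Atp6v0e 99.2 ± 3.13 against 125.7 ± 6.23 CPM (SD, n = 3 each).

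For these 2 lists fry gave adjusted p-values of 0.821 for the lysosomal list and 0.379 for the V-ATPase. No gene of the 36 lists passed the threshold over all genes. When adjusted over the list alone, 0 lysosomal genes and 2 V-ATPase genes, Atp6v0d2 and Atp6v0e, were past 0.05.

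The other lists of clearance and autophagy did not pass in camera. Of 51 autophagy genes, 36 were negative with a median log2 fold change of -0.05 (adjusted p = 0.114), and the 3 Abca4KO libraries lay below the 3 WT libraries in mean level. Without WT 2 the autophagy list passed as lower (adjusted p = 0.0386). Rb1cc1, which starts autophagosome formation, measured 72.6 ± 9.89 against 54.7 ± 3.67 CPM (SD, n = 3 each). Lysosome signalling genes (43 tested, median 0.03) had an adjusted p of 0.884. Outer segment phagocytosis genes (36 tested, median 0.02) had an adjusted p of 0.422. Their mean level was 6.694 to 6.743 log2 CPM in WT and 6.746 to 6.811 in Abca4KO, without overlap (exact permutation p = 0.1). Examples of this list went both ways. Mfge8, a bridging ligand for outer segments, measured 102.9 ± 16.3 against 172.5 ± 31.8 CPM, and the integrin subunit Itgav 917 ± 64.0 against 738 ± 35.9 CPM (SD, n = 3 each). In these 3 lists 0 genes were past 0.05 adjusted over the list alone.

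Lipid lists did not shift as wholes. Cholesterol synthesis genes (24 tested, median log2 fold change -0.02) had an adjusted p of 0.755, and sphingolipid metabolism genes (28 tested, median 0.01) one of 0.655. The list of cholesterol efflux and lipoprotein handling (21 tested, median -0.05) had an adjusted p of 0.531 in camera, while fry's test for change in either direction gave an adjusted p of 0.00292. In it 3 genes were past 0.05 adjusted over the list alone, all lower. The endocytic receptor Lrp2 measured 330.5 ± 12.4 against 246.0 ± 13.5 CPM, its relative Lrp1 2228 ± 67.0 against 1715 ± 68.3 CPM and the cholesterol exporter Abca1 188.4 ± 5.86 against 154.1 ± 4.27 CPM (SD, n = 3 each). Over all genes their adjusted p-values were 0.369, 0.486 and 0.526. The synthesis and sphingolipid lists had 0 genes past 0.05 adjusted over the list alone.

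RPE function lists did not pass with all 6 libraries, and for several of them leaving out 1 library or another changed this. RPE identity markers (36 tested, median 0.04) had an adjusted p of 0.189, with Kcnj13, a potassium channel gene, at 243.3 ± 15.2 against 316.3 ± 17.3 CPM (SD, n = 3 each). Visual cycle genes (21 tested) had a median of -0.04 while camera gave the direction up (adjusted p = 0.755). Lrat, which makes retinyl esters, measured 1797 ± 289.0 against 1389 ± 102.1 CPM (SD, n = 3 each). Oxidative stress genes (38 tested, median 0.08) had an adjusted p of 0.218, and 1 of them, Gpx3, was past 0.05 adjusted over the list alone. The adjusted p was 0.531 for the unfolded protein response (25 tested, median 0.07), 0.0573 for nuclear-encoded oxidative phosphorylation (73 tested, median 0.04) and 0.0526 for mitochondrially encoded mRNAs (13 tested, median 0.16). Circadian clock genes (22 tested, median -0.12) had an adjusted p of 0.0687, and immediate early genes (27 tested, median -0.11) one of 0.887. Extracellular matrix and mesenchymal transition genes (29 tested, median 0.09) had one of 0.486, with Lamb1 lower and past 0.05 adjusted over the list alone. When single libraries were left out, mitochondrially encoded mRNAs passed as higher in 3 of 6 fits (adjusted p 4.73e-04 to 0.625), oxidative phosphorylation in 2 (7.07e-04 to 0.726), RPE identity in 2 (0.00332 to 0.384) and oxidative stress in 1 (0.0397 to 0.695). Circadian clock genes passed as lower in 1 (0.00238 to 0.408), and immediate early genes as higher in 1 and as lower in 1 (0.00609 to 0.686). The other 7 lists of RPE function and stress had 0 genes past 0.05 adjusted over the list alone.

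Lists of endothelial markers and of fibroblast and sclera markers rose in camera with the preset correlation only. All 19 endothelial markers were positive, with a median log2 fold change of 0.59, with an adjusted p of 1.63e-11 (0.823 with an estimated correlation). Their mean levels overlapped between the genotypes, with WT 2 at 5.09 and Abca4KO 2 at 5.01 log2 CPM (exact permutation p = 0.2). Vwf, the von Willebrand factor gene, measured 51.3 ± 11.5 against 98.9 ± 31.5 CPM, and the transcription factor gene Sox18 15.01 ± 1.83 against 25.7 ± 6.53 CPM (SD, n = 3 each). Fibroblast and sclera markers (20 tested, 16 positive, median 0.21) had an adjusted p of 9.35e-05 (0.823 with an estimated correlation; exact permutation p of the mean level 0.1), with the collagen gene Col3a1 at 115.1 ± 11.6 against 169.5 ± 6.06 CPM (SD, n = 3 each). Adjusted over the list alone, 0 endothelial markers and 1 fibroblast marker, Col3a1, were past 0.05. Mural cell markers (13 tested, median 0.09) had an adjusted p of 0.189, and melanocyte markers (12 tested, median 0.31) one of 0.0526, with the latter past the threshold as higher in 2 of the 6 fits that left out a library. No mural cell marker was past 0.05 adjusted over the list alone. Among melanocyte markers, Mlana was higher and Kit lower past 0.05 adjusted over the list alone. Mlana is also in the RPE identity list, where it was not past 0.05, and Kit is also in the lymphocyte and mast cell list.

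Immune lists gave mixed results. Macrophage and microglia markers rose in camera with the preset correlation (24 tested, 16 positive, median 0.22, adjusted p = 0.0132; adjusted p = 0.915 with an estimated correlation), and their mean levels overlapped between the genotypes (exact permutation p = 0.4). The lysosomal cathepsin gene Ctss measured 370.5 ± 191.9 against 992 ± 352 CPM and Cd68 94.6 ± 26.7 against 181.9 ± 47.5 CPM (SD, n = 3 each), whereas Csf1r had a log2 fold change of -0.12. The complement list rose (31 tested, 24 positive, median 0.18, adjusted p = 0.00630; adjusted p = 0.823 with an estimated correlation). Its examples included C3ar1, a complement receptor gene, at 17.3 ± 4.98 against 34.8 ± 6.36 CPM (SD, n = 3 each). Mean levels of the complement list overlapped between the genotypes (exact permutation p = 0.3). The macrophage call was lost without WT 3 (adjusted p = 0.579) and without Abca4KO 2 (0.242), and the complement call without WT 3 (0.0669) and without Abca4KO 2 (0.108).

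The interferon response list fell (32 tested, 31 negative, median -1.09, adjusted p = 0.0171; adjusted p = 0.945 with an estimated correlation). WT 2 stood apart: its mean level was 6.10 log2 CPM, against 3.51 and 3.01 in the other WT libraries and 3.54 to 4.02 in the Abca4KO libraries. Without WT 2 the list turned to higher in Abca4KO (adjusted p = 3.96e-04), and the call was lost without Abca4KO 1 (0.123) and without Abca4KO 3 (0.0508). Gbp3, an interferon-induced GTPase gene, measured 375 ± 573.6 against 46.3 ± 6.72 CPM (SD, n = 3 each). Antigen presentation genes had the same outlying library, at 8.55 log2 CPM in WT 2 against 4.55 to 6.81 in the others. All 20 had negative log2 fold changes, with a median of -0.88, while camera gave the direction up (adjusted p = 0.864) and the mean level was 0.09 higher in Abca4KO. That list passed as higher without WT 2 (adjusted p = 2.74e-14) and as lower without WT 3 (0.0173). Inflammasome and cytokine genes (22 tested, median -0.40) had an adjusted p of 0.697, and passed as higher without WT 2 (0.00992) and as lower without WT 3 (5.21e-04). Lymphocyte and mast cell markers (19 tested, median -0.37) had one of 0.952, with Kit lower and past 0.05 adjusted over the list alone. In no other immune list of this paragraph was a gene past 0.05 adjusted over the list alone, nor in the macrophage or complement lists.

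Markers of neighbouring neural and other tissue were variable between libraries. Rod photoreceptor markers (30 tested, median 0.41, adjusted p = 0.0935) had mean levels of 4.34 to 5.60 log2 CPM in WT and 4.804 to 6.44 in Abca4KO, highest in Abca4KO 1. The rod list passed as lower without that library (adjusted p = 0.0329) and as higher in 4 of the other 5 fits that left out a library, at a lowest adjusted p of 1.92e-05 without Abca4KO 2. Cone markers (13 tested, median 0.13) had an adjusted p of 0.655. Inner retinal neuron markers rose (19 tested, 14 positive, median 0.33, adjusted p = 0.0381; adjusted p = 0.823 with an estimated correlation), and 1 of them, Tfap2a, was past 0.05 adjusted over the list alone. That call was lost without WT 1 (0.163), WT 2 (0.384), Abca4KO 1 (0.0856) or Abca4KO 3 (0.0806). WT 3 had the highest mean level of these neuron markers, at 2.94 against 2.14 to 2.87 log2 CPM in Abca4KO (exact permutation p = 0.4). Skeletal muscle markers rose (21 tested, 15 positive, median 0.36, adjusted p = 0.00750; adjusted p = 0.915 with an estimated correlation). That call was lost without WT 1 (0.538), WT 2 (0.209) or Abca4KO 2 (0.0541). Of the rod, cone and skeletal muscle markers, 0 were past 0.05 adjusted over the list alone.

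Muller glia and astrocyte markers (18 tested, 13 negative, median -0.25) had an adjusted p of 0.0687 in camera, and fry's test for change in either direction gave 0.0152. They passed as lower in 3 of the 6 fits that left out a library (adjusted p 0.0120 to 0.415). Adjusted over the list alone, the transcription factor gene Hes1 was higher, at 42.5 ± 4.68 against 72.7 ± 9.16 CPM, and Dapl1 lower, at 45.5 ± 3.73 against 33.9 ± 2.91 CPM (SD, n = 3 each). Haemoglobin and blood cell genes (7 tested, median 0.25) had an adjusted p of 0.228 and passed as higher in 1 of those 6 fits (0.0468), and lens crystallins (7 tested, median 0.08) one of 0.952. Schwann cell and myelin markers (13 tested, median -0.01) had an adjusted p of 0.589 and iris and ciliary epithelium markers (12 tested, median -0.01) one of 0.755, both with the camera direction up against a negative median. Adjusted over the list alone, Pmp22 and Aqp1 were higher in these 2 lists, and 0 genes of the blood and lens lists were past 0.05.

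**Figure D2:**
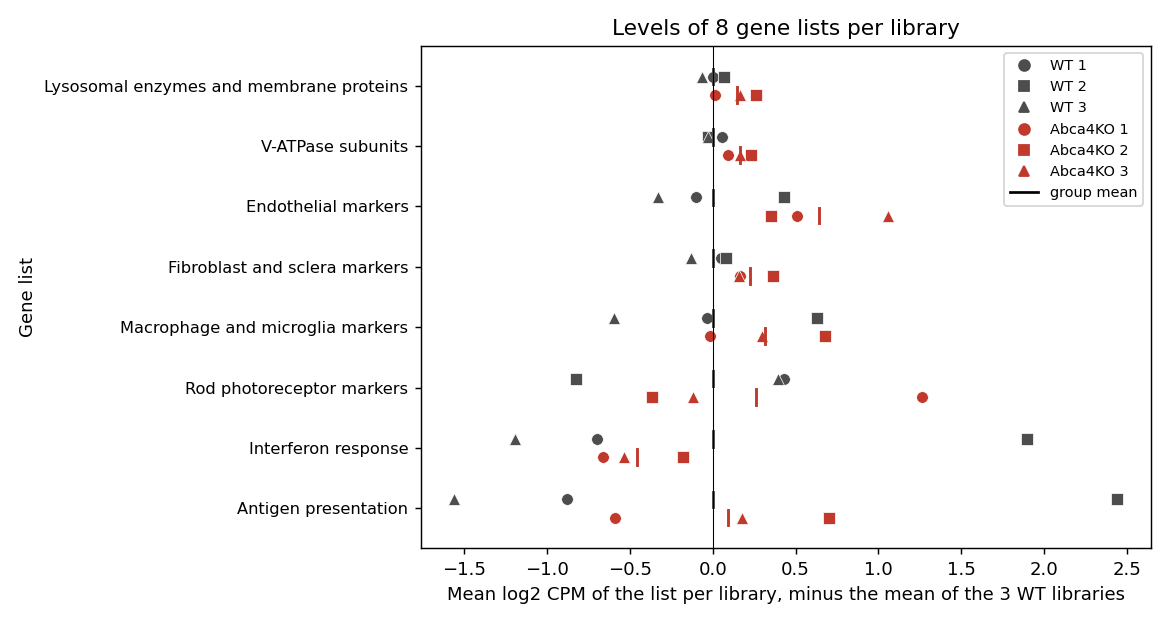
Mean log2 CPM of 8 gene lists per library (horizontal axis, relative to the mean of the 3 WT libraries), with grey for WT, red for Abca4KO, shapes for replicates and bars for group means. The 3 Abca4KO libraries lie above the 3 WT libraries for the V-ATPase (6.72 to 6.87 against 6.60 to 6.69 log2 CPM) and for fibroblast and sclera markers, whereas WT 2 is the highest library for interferon and antigen presentation genes. For antigen presentation the 3 Abca4KO libraries (5.52 to 6.81) also lie above WT 1 (5.23) and WT 3 (4.55).

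Of the 36 lists, 9 passed in camera with the preset correlation, 8 higher and 1 lower. With an estimated correlation 0 passed in camera, at a smallest adjusted p of 0.823, and 0 were at an unadjusted p under 0.05. Fry called 0 lists for a shift in 1 direction, with 2 at an unadjusted p under 0.05. The calls for lysosomal, V-ATPase, endothelial and fibroblast lists held in all 6 fits that left out a library. Those fits shared libraries and kept the preset correlation of 0.01, whereas the estimates for these lists were 0.33, 0.12, 0.77 and 0.22. With the preset correlation, each of the 10 splits of the 6 libraries into equal groups gave at least 9 lists, and the highest other split gave 18. The repeated calls therefore cannot tell a genotype effect from other differences between libraries.

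Genes with low p-values were not spread evenly over the genome. Of 276 tested genes starting between 80 and 100 Mb on chromosome 3, 22 (7.97%) had an unadjusted p under 0.01, 8 higher and 14 lower in Abca4KO. On the other chromosomes 239 of 16456 (1.45%) did so (2-sided Fisher's exact test p = 4.07e-10). On the rest of chromosome 3 it was 15 of 608 (2.47%), Abca4 among them. The stretch holds, among others, Bcan, Npr1, Gucy1a1, Tpm3, Ctss, Lrat and Phgdh, of which Bcan and Npr1 passed the threshold. Of the calls outside it, Tpm3-rs7, Gm9347 and Gm7901 are near-identical to Tpm3 or Phgdh, while Slco1c1 and Cep83os lie on other chromosomes. The stretch was chosen after the values were seen, and genes are not independent replicates.

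**Figure D3:**
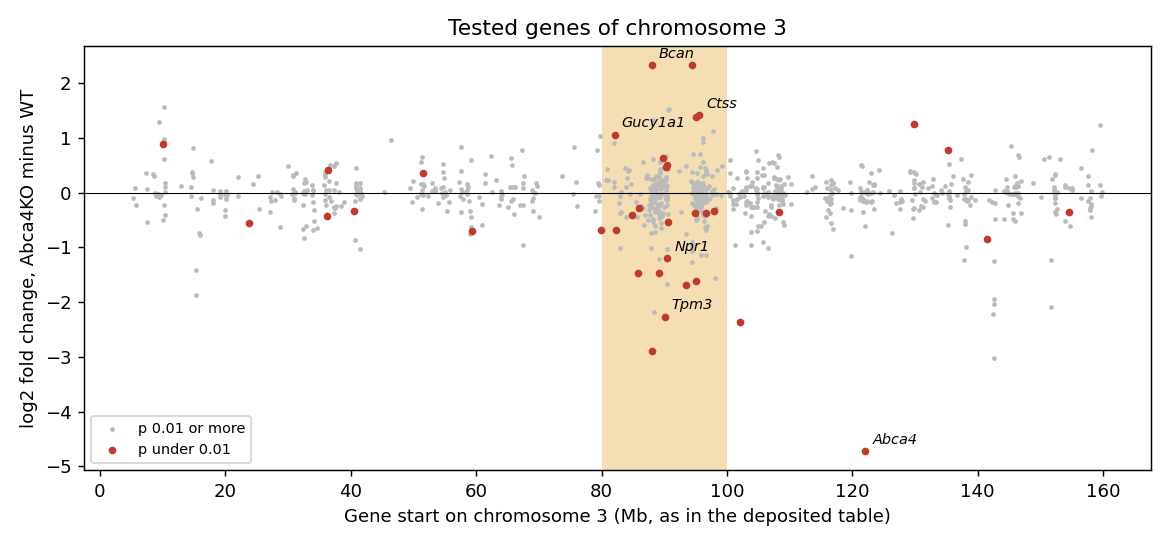
Log2 fold change, Abca4KO minus WT, of each tested gene against its start on chromosome 3 in Mb, with red points for genes at an unadjusted p under 0.01 and shading from 80 to 100 Mb. Of the 276 genes in the shaded stretch 22 are red, and Abca4 lies outside it at -4.72.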

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

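The fit without WT 2 and Abca4KO 1, the robust fit and the fit without chromosome 3 were chosen after seeing the data; the others were planned. The Abca4 log2 fold change kept its direction and passed in every alternative fitted to it, with values of -4.78 to -4.65 over the fits that left out a library. The 8 calls were kept with other size factors, with a filter of 1 CPM, and without the 100 most abundant genes in the scaling, and no scaling moved the median log2 fold change by more than 0.0146. Called genes numbered 19 with no filter (12 higher, 7 lower), 106 with DESeq2 (63 higher, 43 lower), 31 with limma-voom and sample weights (14 higher, 17 lower) and 25 with the rod marker covariate (15 higher, 10 lower), and each of these included the 8. They numbered 5 against a 1.5-fold change (1 lower) and 5 without chromosome 3 (0 lower), the latter from fewer genes tested. With single libraries left out they numbered 3 to 11 (2 to 6 higher, 1 to 5 lower). Without WT 2 and Abca4KO 1 there were 190 calls (118 higher, 72 lower), the highest of the 9 ways to leave out 1 library of each genotype, where the other 8 gave 1 to 11. The robust fit kept 7 of the 8, lost Tpm3-rs7 and gained Gucy1a1. Gucy1a1 also passed with no filter, with limma-voom and sample weights and with the rod marker covariate. For these changes the cause was not tested. Same-numbered libraries deviated from their group means with correlations of 0.29, 0.43 and -0.15, and not every library correlated best with its own number. With 3 libraries per genotype these correlations depend on each other, so they neither show nor exclude pairing by number. With the number as a block, 9 genes and 15 lists were called, against 8 and 9. Cep83os was lost, and Cd163l1 and Tpm3 were gained. Lists gained in camera were rod (adjusted p = 6.01e-05), mitochondrially encoded (4.75e-04), inflammasome and melanocyte (0.0156 each), and oxidative phosphorylation and Muller glia lists (0.0264 each). Called lists numbered 0 with an estimated correlation, 8 to 14 with single libraries left out and 18 without WT 2 and Abca4KO 1. Fry called 0 for a shift in 1 direction and 2 for change in either direction.

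Of 153 followed genes, 18 changed sign in at least 1 alternative, and of 36 lists 16 changed direction. Among them 2 gene values and 9 list values were past the threshold in at least 1 of the fits compared. The log2 fold changes over the fits that left out a library were -0.10 to 0.043 for Optn, -0.16 to 0.033 for Rpe65, -3.54 to 0.077 for Gbp3, -2.45 to 0.15 for Irf7, -3.15 to 0.36 for Oas3, -2.59 to 1.41 for Tap1, -2.22 to 0.85 for Ciita, -1.37 to 0.25 for Tap2, -1.87 to 1.02 for H2-T23, -3.17 to 0.98 for Ccl5, -3.15 to 1.01 for Cxcl10, -0.14 to 0.94 for Rcvrn, -0.28 to 1.04 for Sag, -0.18 to 0.92 for Guca1b, -0.31 to 0.80 for Hbb-bt and -6.34 to 0.78 for Aqp5. Without WT 2 and Abca4KO 1 they were 0.029 for Gbp3, 0.14 for Irf7, 0.46 for Oas3, 1.65 for Tap1, 1.07 for Ciita, 0.36 for Tap2, 1.25 for H2-T23, 1.29 for Ccl5, 1.11 for Cxcl10, -0.40 for Rcvrn, -0.62 for Sag, -0.53 for Guca1b, 0.14 for Mal and 1.30 for Aqp5. With limma-voom and sample weights they were 0.80 for Tap1, 0.32 for Ciita, 0.51 for H2-T23, 0.52 for Ccl5, -0.063 for Sag, -0.059 for Guca1b, -0.0031 for Cryab, 0.066 for Mal and 0.73 for Aqp5.

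The adjusted p-values of lists over the fits that left out a library were 0.352 to 0.994 for lens crystallins, 2.74e-14 to 0.959 for antigen presentation, 0.191 to 0.954 for iris, 0.0669 to 0.897 for lymphocyte, 0.538 to 0.947 for lysosome signalling, 0.218 to 0.897 for visual cycle, 0.00332 to 0.384 for RPE identity, 0.00609 to 0.686 for immediate early, 4.72e-08 to 0.123 for interferon, 5.21e-04 to 0.911 for inflammasome, 1.92e-05 to 0.196 for rod, 0.199 to 0.632 for cone, 0.0506 to 0.994 for unfolded protein response, 0.0468 to 0.994 for haemoglobin and 0.125 to 0.958 for Schwann cell genes. Directions turned without WT 2 and Abca4KO 1 for lens crystallins (0.717), lymphocyte (0.0987), lysosome signalling (0.475), visual cycle (0.188), RPE identity (0.717), sphingolipid (0.992), immediate early (5.43e-04), interferon (1.26e-05), inflammasome (0.00154), rod (5.86e-23) and cone lists (0.0694). They turned with the replicate block for antigen presentation (0.0801) and iris (0.792), with fry for lens crystallins (0.980), and with the 1 CPM filter for lens crystallins (0.803) and lymphocyte markers (0.803). For these turns the cause was not tested. At these depths and with 3 libraries per genotype, 6.57% of simulated 1.5-fold changes were recovered; depth was not varied.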

Other observations

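The tests on neighbours of Abca4, on summed counts of copies and on other splits of the libraries were chosen only after the results were seen. The immunoglobulin gene Igkc, the kappa constant region, measured 489.3 and 308.4 CPM in Abca4KO 2 and 3, against 41.2 in Abca4KO 1 and 9.58 to 50.1 in WT. Ighg2c, chosen after its values were seen, measured 16.2 and 27.5 CPM in Abca4KO 2 and 3, against 1.07 in Abca4KO 1 and 0.161 to 0.209 in WT. Neither passed the threshold with all libraries (adjusted p = 0.616 and 0.393, edgeR quasi-likelihood test), but Ighg2c passed with no filter, without Abca4KO 1 and with the rod marker covariate. In WT 2, which had the highest interferon and antigen presentation levels, the surface epithelial genes Krt5 and Aqp5 measured 199.3 and 73.9 CPM, against 0.697 to 32.5 and 0.105 to 3.56 CPM in the other libraries.

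The first pattern was the cluster of low p-values on chromosome 3 between 80 and 100 Mb. A scan of stretches of 20 Mb over all tested chromosomes gave p = 0.001 for it, the smallest that the 1000 permutations of genes can give. Such permutations treat neighbouring genes as independent and do not measure the spread between mice. The genes nearest Abca4 showed no excess of low p-values. Within 10 Mb of it, 1 of 97 genes (1.03%, 95% interval 0.026% to 5.61%) had an unadjusted p under 0.01, against 1.45% on other chromosomes (2-sided Fisher's exact p = 1). The stretch lies outside those 10 Mb, so an effect of the targeted allele on its neighbours would have to pass over the nearest genes. Their upper limit of 5.61% also lies below the 7.97% of the stretch. Both argue against such an effect for the cluster. They do not exclude it, since the stretch was chosen for its high share and its own 95% interval reaches down to 5.06%. A stretch that comes from another strain in the Abca4KO line may also give low p-values to pseudogenes elsewhere whose parent gene lies in it, and without the 3 Phgdh pseudogenes already noticed 1 of 10 such pseudogenes against 1 of 667 others had them (1-sided Fisher's exact p = 0.0293). That rests on Gm7665 alone, a copy of S100a11 with a negative log2 fold change and an uncertain count, and the mice of the groups came from different lines, so an effect of Abca4 loss stays open and untested.

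The second pattern was that Tpm3-rs7 and the Phgdh pseudogenes Gm9347 and Gm7901 rose, while Tpm3 and Phgdh lie in that stretch. Reads moving between near-identical copies are a candidate explanation for both families. Tpm3 and Tpm3-rs7 summed to 153.8 ± 59.5 CPM in WT and 138.6 ± 23.4 CPM in Abca4KO (SD, n = 3 each), a log2 fold change of -0.15 (SE 0.26), where the gain of Tpm3-rs7 with Tpm3 unchanged would have given 0.72. The sum lay within 2 SE (0.52) of no change and further than that below 0.72. This argues against a rise of Tpm3-rs7 with Tpm3 unchanged, but the sum cannot tell moved reads from opposite changes of both genes. Phgdh and its copies summed to 403.1 ± 29.8 and 384.0 ± 38.4 CPM (SD, n = 3 each), a log2 fold change of -0.070 (SE 0.10), while the copies gained 49.3 CPM and Phgdh alone measured 396.4 in WT and 328.0 in Abca4KO. That gain with Phgdh unchanged would have given only 0.17, within 2 SE (0.20), so the summed Phgdh counts cannot tell moved reads from a rise of the copies. Of the 10 copies of Phgdh with counts, 8 had more counts in Abca4KO and 1 had fewer. Gm9347, Gm7901 and Gm13337, another copy, lie on chromosomes 7, 8 and 2. Gm13337 had 0 counts in WT and 103 in Abca4KO, and a change in the copies' own expression was not tested.

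The third pattern was the small rise of lysosomal genes. More macrophages in the Abca4KO samples may account for part of it. Of 24 macrophage markers 16 had positive log2 fold changes and 8, Csf1r, Ptprc and Cx3cr1 among them, negative ones, and none passed the threshold. The mean lysosomal level was 0.15 log2 units higher in Abca4KO (SE 0.08), and 0.093 higher (SE 0.05, 95% interval -0.08 to 0.27) with the mean macrophage level as a covariate; the lists share 0 genes. The unadjusted difference was itself not clear of 0, with overlapping levels and an exact permutation p of 0.2. With 6 libraries the adjusted difference was neither clear of 0 nor far below the unadjusted one, so that macrophage content and a change within RPE cells cannot be told apart here. The V-ATPase level was 0.16 higher (SE 0.05), and 0.15 higher (SE 0.06, 95% interval -0.04 to 0.33) with the same covariate, so its difference moved little and its interval also includes 0. The endothelial and fibroblast lists were higher as well, and their share in the lysosomal rise was not tested.

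The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 8 genes and the highest of the others 10, so that 2 of the 10 splits gave at least as many. At an unadjusted p under 0.05 the real split gave 1217 genes and the highest of the others, WT 1, WT 3 and Abca4KO 1 against the rest, 2740. The remaining splits gave 253 to 1131 genes. For lists the real split gave 9 and the highest of the others 18, and all 10 splits gave at least as many.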
